A study of Danio rerio and Homo sapiens with 21 samples.

How the data were processed

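The series holds 21 samples of 4 kinds. There were 12 droplet single-cell RNA libraries from zebrafish, of which 8 came from adult kidney marrow, the blood-forming organ of the adult fish, and 4 from whole embryos at 96 hours post fertilisation kept at 28 °C. A further 4 bulk RNA and 3 bulk ATAC libraries came from HUVEC, primary human umbilical vein endothelial cells, carrying the adenoviral gene E4ORF1, and 2 single-cell ATAC libraries came from kidney marrow. Per the labels' protocols, kidney marrow was dissected and its red cells were lysed before loading, embryos were dissociated with Liberase, and HUVEC at 37 °C were starved for 8 hours and then given recombinant human CXCL8 or PBS for 6 hours before a ribosomal-depletion RNA kit was applied. The labels call the kidney control mcs, and how the prkcda and cxcl8 fish were made is not given in the sources used here.

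For the zebrafish RNA the authors deposited UMI counts per gene and cell barcode, with barcodes and gene symbols in separate lists of other kinds of value. Per the submitters' processing notes these came from Cell Ranger 4.0 and GRCz11, and the barcodes had already been reduced to those called cells. Some feature lists ended in 6 transgene or reporter sequences. For HUVEC RNA the authors deposited RSEM expected counts per gene together with TPM values, on GRCh38 per the submitters' processing notes, and the expected counts were not normalised. For HUVEC ATAC the authors deposited 1 peak list per library, not pooled, with the enrichment ratio of each peak and its −log10 p-value and −log10 q-value. The peak caller is not given in the sources used here, and no peak had a p-value above 0.01. For kidney marrow ATAC the authors deposited counts of transposition events per peak and cell barcode from Cell Ranger ATAC 1.2, per the submitters' processing notes, and each library had its own peak positions.

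Cells with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, and doublets were called per library with Scrublet (in scanpy 1.11.5) at an expected 0.8% per 1000 cells, with 30 principal components, and removed. Each of the 4 single-cell RNA experiments (kidney July, kidney November, embryo runx and embryo August, named from the sample titles) was clustered alone from counts scaled to 10000 per cell on a log scale, with 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 (leidenalg 0.10.2) and random seed 1, under Python 3.11.15, anndata 0.12.19 and scikit-learn 1.9.0. Clusters were given a class name ending in "-like" in the sense of resembling it, from marker lists for 13 kidney and 26 embryo classes. A marker counted when at least 5% of the cluster's cells had it and its mean lay at least 2-fold above that of the median cluster, and a name needed 3 such markers, a score of 0.5 and no contradicting genes among the 10 leading genes. This naming rule was revised after the clusters had been seen and before any comparison between groups, so the shares of clusters it left without a name are given beside the shares it affects. Class names below stand for such clusters.

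UMI counts were summed per library and class, and cells were not treated as replicates. Within each kidney class, genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr, two-sided, Benjamini-Hochberg over the genes of a class) where at least 3 of the 4 libraries of an experiment held 20 or more cells of the class, using all kidney libraries with 20 or more so that they shared an estimate of the spread. The embryo fit required all 4 libraries and carried the experiment as a term. Numbers of cells per class were tested with the same edgeR test with the cells per library as offset. HUVEC genes were tested likewise on rounded expected counts, with 229 XIST and Y-linked genes left out. Gene lists, 22 human and 15 zebrafish, were set for tests with camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation), with fry beside it in HUVEC, and adjusted over all lists and classes of a comparison. A list needed 3 measured members, which the human leukocyte list did not reach, so it was not tested. The estimated setting also rests on few residual degrees of freedom (2 in HUVEC). A list that fails only there is thus not shown to fail because its genes vary together, nor is its call shown to hold. DESeq2 1.42.0 served as an alternative, and all models ran under R 4.3.3. The threshold was an adjusted p of 0.05 throughout. With 2 libraries against 2, an exact permutation test of a single value cannot give a p below 0.333, so none is reported.

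On simulated data with 200 changed genes, the HUVEC design recovered 1% of 2-fold and 52% of 4-fold changes, with 11.7% of its calls false. The July neutrophil design recovered 65% and 91%, with 7.7% false, the November tubule design 12% and 43%, with 1.80% false, and the embryo epidermis design 37% and 86%, with 15.2% false. The test of July class shares recovered 99% of 3-fold changes and called 1.88% of the unchanged classes, at a spread that was chosen rather than fitted. The November and embryo shares were not simulated. The labels do not say that libraries of 1 group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. No pair of kidney RNA or HUVEC RNA libraries of 1 group agreed within sampling noise over genes, with chi-square per degree of freedom between 3.24 and 158.88. Embryo libraries were not compared in this way.

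The number of usable cells differed between experiments. The cells used numbered 2145 and 2175 in the July mcs libraries and 2851 and 3418 in the July prkcda libraries. They numbered 249 and 294 in the November mcs libraries and 156 and 184 in the November cxcl8 libraries. In November the gene minimum alone removed 34.2% to 45.8% of barcodes. The mitochondrial limit removed a further 663 of 1684 and 776 of 1947 in mcs and 379 of 855 and 416 of 931 in cxcl8. The precision of a November share is therefore lower. Group comparisons, gene lists, cell class markers, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Genes named below are the manipulated genes with their receptors and transgenes, the 4 higher and 4 lower genes with the smallest p in the 4 classes with most calls and in HSPC and endothelial classes, up to 10 higher and 10 lower genes in HUVEC, and the 4 members of each list with the smallest p. Genes that define a class are not named as results within it, but counts over classes, as for the haemoglobin genes, include it. Several genes that this rule names are not reported here.

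Alternatives were other normalisations, tools, filters, cell filters, clustering at resolution 2, doublets kept, the replicate number as a block, each library left out, other denominators and other peak overlaps. Peaks were compared by overlap of at least 1 base with bedtools 2.31.1, and with a reciprocal overlap of 50%. Intervals are exact 95% binomial or Poisson intervals (scipy 1.17.1) and cover counting error only. A gene with no counts in 1 group is given a bound from a floor of 3 counts over the group. Peaks were not assigned to genes here because no genome annotation was used. Figures were drawn with matplotlib 3.10.9.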

Results

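Single-cell RNA was measured in 8 kidney marrow and 4 whole-embryo zebrafish libraries, bulk RNA and open chromatin (ATAC) in HUVEC, and single-cell ATAC in kidney marrow. The July kidney experiment held 2 mcs and 2 prkcda libraries, and the November experiment 2 mcs and 2 cxcl8 libraries. The runx and August embryo experiments each held 1 control and 1 cxcl8 library. HUVEC RNA came from 2 PBS and 2 CXCL8 libraries and HUVEC ATAC from 3 libraries, while single-cell ATAC came from 1 mcs and 1 prkcda library. The July mcs libraries held 18650659 and 18483127 UMIs (counted RNA molecules) in 3448 and 3269 barcodes, and the July prkcda libraries held 15807724 and 18246877 in 3896 and 4665. In November the mcs libraries held 5587840 and 6560228 UMIs in 1684 and 1947 barcodes, and the cxcl8 libraries 2715387 and 2889613 in 855 and 931. The embryo control and cxcl8 libraries held 28636848 and 41170427 UMIs in runx and 88220585 and 85564562 in August, in 3365, 4729, 10833 and 7109 barcodes. Expected counts summed to 35568752 and 26748070 in the PBS libraries and to 31930330 and 30362043 in the CXCL8 libraries. Gene levels are given as CPM, counts scaled to the TMM-adjusted library size and averaged over libraries.

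The comparison of prkcda with mcs kidney marrow asks how blood-forming tissue differs in the fish labelled with prkcda, the gene for protein kinase C delta, a signalling kinase. Red cells (erythroid class) made up a larger share of prkcda than of mcs cells, and so did neutrophils, the granule-bearing white cells, and NK-like lymphocytes. Haematopoietic stem and progenitor cells (HSPC) and kidney tubule cells made up smaller shares. These 5 of 10 classes passed. Both prkcda libraries lay on 1 side of both mcs libraries in every class but stromal, whether it passed or not. The erythroid share was 1.62% ± 0.21 (SD, n = 2 libraries) in mcs and 11.6% ± 1.0 in prkcda (log2 change 2.84 ± 0.16 SE, edgeR adjusted p = 1.40e-17). Neutrophils made up 20.9% ± 0.35 in mcs and 34.0% ± 0.59 in prkcda (log2 change 0.71 ± 0.08, adjusted p = 6.45e-10), and among haematopoietic classes alone the change was 0.21 ± 0.03 (adjusted p = 7.75e-04). HSPC made up 12.8% ± 1.1 and 5.66% ± 0.22 (log2 change −1.17 ± 0.12, adjusted p = 1.48e-10), and tubule cells 13.5% ± 1.3 and 6.55% ± 0.16 (log2 change −1.05 ± 0.12, adjusted p = 4.82e-10). The HSPC change was smaller at clustering resolution 2 (−0.36), with stricter cell filters (−0.40) and with doublets kept (−0.38), and passed in each. NK-like cells made up 0.72% ± 0.30 and 1.79% ± 0.55 (log2 change 1.28 ± 0.32, adjusted p = 7.69e-04). That call was lost without mcs 1 (1.78, adjusted p = 0.0526) and without mcs 2 (0.91, adjusted p = 0.159). Multiciliated cells (3.91% and 2.94%), thrombocytes (0.51% and 0.28%), eosinophils or mast cells (6.41% and 7.22%), endothelial cells (0.93% and 1.15%) and stromal cells (2.55% and 2.52%) did not pass, with adjusted p from 0.0541 to 0.876. Multiciliated cells passed with stricter cell filters (log2 change −1.11), with unnamed clusters counted with their best class (−1.33), with doublets kept (−0.45), with only the July libraries (−0.42) and without prkcda 1 (−0.51). Thrombocytes passed with stricter cell filters (−1.13), with all deposited barcodes (−1.28) and among haematopoietic classes (−1.37). Eosinophils or mast cells passed in opposite directions, at −0.45 with clustering resolution 2, 0.32 without erythroid cells in the total and 0.31 with all deposited barcodes. These are shares of 4320 mcs and 6269 prkcda cells.

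The clusters behind a class differed between groups. In mcs, 74.4% of neutrophils lay in a cluster led by lyz (lysozyme), lect2l and npsn, which held 10.6% of prkcda neutrophils. In prkcda, 64.6% lay in a cluster led by mpx (myeloperoxidase), ved and ch25hl2, which held 0.78% of mcs neutrophils. A cluster led by slc12a3, a salt transporter of the distal tubule, held 42.0% of mcs and 16.6% of prkcda tubule cells. Cells left without a name made up 36.2% of mcs and 26.3% of prkcda cells. Those scoring highest for HSPC but kept out by the naming thresholds made up 3.91% of mcs and 9.64% of prkcda, those for neutrophils 0.53% and 7.14%, those for tubule 9.11% and 1.02%, and those for multiciliated cells 14.9% and 4.59%. When such clusters were counted with their best class, the HSPC share was 16.7% in mcs and 15.3% in prkcda, and that difference did not pass (log2 change −0.13, adjusted p = 0.164). Median UMIs per neutrophil were 2249 and 2465 in the mcs libraries and 1506 and 1271.5 in the prkcda libraries, and per HSPC they were 15425 and 14568 against 10425 and 10011.

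**Figure D1:**
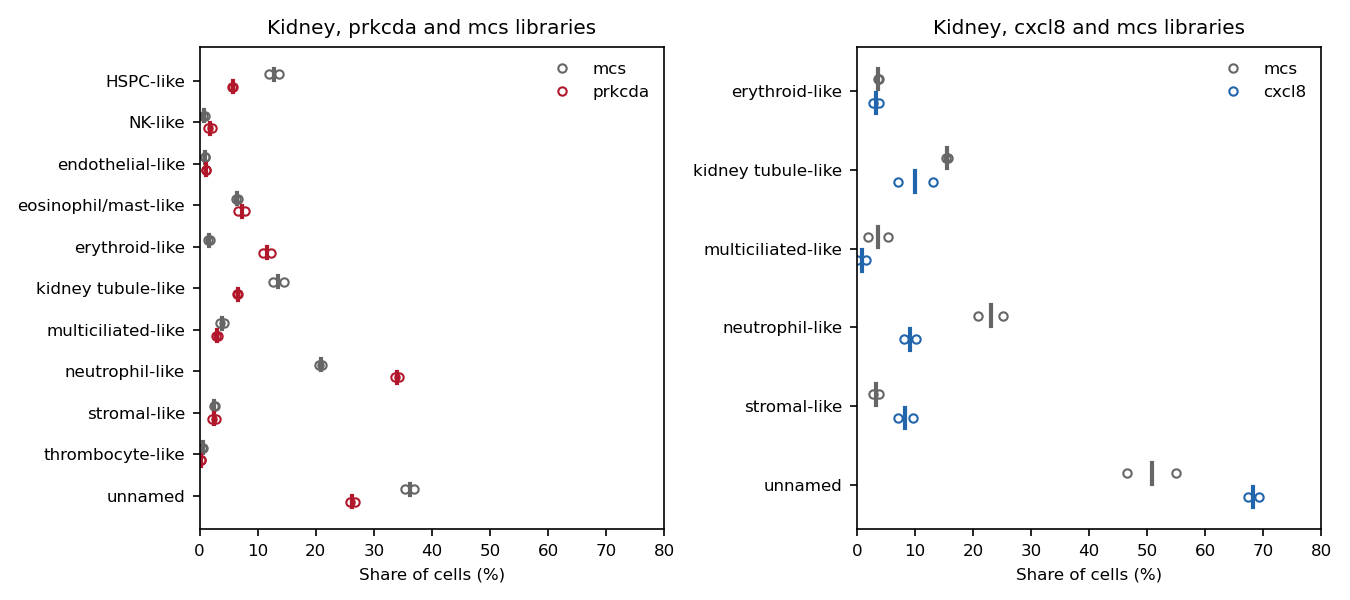
Share of cells in each class (%, horizontal axis) in the July libraries (left) and the November libraries (right), with a point per library and bars at the group means. In July the erythroid bar reached 11.6% in prkcda against 1.62% in mcs, and in November the neutrophil bar reached 9.20% in cxcl8 against 23.0% in mcs.

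Within classes, 7 of 10 neutrophil granule genes, 13 of 19 immediate early and heat shock genes and 55 of 81 ribosomal genes rose in prkcda HSPC, and 30 of 81 ribosomal genes fell in prkcda neutrophils. None of these lists passed with an estimated correlation (camera adjusted p = 0.315, 0.315, 0.570 and 0.568). Median mitochondrial shares of UMIs were 2.95% in each mcs library and 4.096% and 4.19% in the prkcda libraries. The count of 4615 pairs of gene and class (2451 higher, 2164 lower in prkcda) came from 39908 tested over 9 classes and covered 3227 genes. Of these, 2384 passed in 1 class and 193 passed in opposite directions in different classes. The haemoglobin genes hbaa1 and hbba1 (ENSDARG00000089087) were called higher in 9 of 9 classes, and hbaa2, hbba2 and a second gene named hbba1 (ENSDARG00000097238) in 8. Neutrophils held a median of 41 and 46 haemoglobin UMIs per cell in the prkcda libraries and 1 in each mcs library. Barcodes under the gene minimum held a median of 38 and 42 in the prkcda libraries. The neutrophil granule genes lyz and lect2l and the early response genes btg2 and dusp1 were called higher in 6 classes, fosab and il1b in 5, and atp5md, cox7c, ndufa3, ost4 and tma7 lower in 6. In barcodes under the gene minimum, lyz and lect2l made up 1.52% and 1.05% of non-mitochondrial UMIs in mcs and 3.05% and 3.23% in prkcda. With the haemoglobin and neutrophil lists left out, 565 of 578 calls were left in HSPC and 492 of 506 in neutrophils. Calls numbered 2911 without mcs 1 and 2949 without prkcda 1, and DESeq2 gave 1811.

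The gene named in the label was tested over all cells summed, a fit added after the data were seen. There prkcda (ENSDARG00000009208) was higher in prkcda libraries, at 42.8 CPM in mcs and 65.8 in prkcda (log2 change 0.62 ± 0.10, adjusted p = 0.00191), and at 41.2 and 50.9 without the TMM adjustment. Its paralogue prkcdb did not pass (log2 change −0.06). The chemokine gene cxcl8b.1 fell from 58.1 ± 26.4 (SD) to 13.4 ± 9.8 (log2 change −2.13, adjusted p = 0.00827), while cxcl8a rose from 1.42 ± 0.90 to 6.40 ± 3.60 (2.16, adjusted p = 0.0143) and the receptor gene cxcr1 rose from 9.24 ± 1.87 to 23.8 ± 0.65 (1.37, adjusted p = 0.0167). Single libraries weigh on these means, as cxcl8b.1 was at 37.6 and 74.5 CPM without TMM in mcs and at 16.0 and 4.90 in prkcda, and cxcl8a at 0.75 and 2.00 and at 3.04 and 6.76. These sums mix classes whose shares differed. Within neutrophils neither prkcda (log2 change −0.26 ± 0.10, adjusted p = 0.108) nor cxcr1 (−0.09) passed, and within HSPC prkcda did not pass (0.27).

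In HSPC the neutrophil granule gene lect2l rose with the early response genes ier2b and btg2, the chaperone gene hsp90aa1.2 and the survival gene mcl1a. The nucleotide synthesis gene rrm2 and the respiratory chain genes atp5md and cox7c fell. Of these lect2l, btg2, atp5md and cox7c recur in 6 classes. Clusters scoring highest for HSPC but kept out held 169 mcs and 606 prkcda cells, against 554 and 356 cells named HSPC. The changes in this class may thus come from which cells were named, which was not tested. The CPM of lect2l went from 30.8 to 151 (log2 change 2.31 ± 0.14, adjusted p = 1.46e-07) and of rrm2 from 80.2 to 8.14 (−3.27 ± 0.20, adjusted p = 2.00e-07). The gene ier2b rose by 1.51, btg2 by 1.26, hsp90aa1.2 by 1.22 and mcl1a by 0.81 on the log2 scale, and atp5md fell by 0.84 and cox7c by 0.67. Of the cytosolic ribosomal proteins 55 of 81 measured rose and 2 fell (camera adjusted p = 6.67e-28, 0.570 with an estimated correlation). Of the immediate early and heat shock genes 13 of 19 rose (8.30e-31, 0.315 with an estimated correlation). Of the ERK target genes, which respond to growth-factor signalling, 9 of 19 rose (2.43e-23, 0.244 with an estimated correlation). Of the neutrophil granule genes 7 of 10 rose (1.57e-26, 0.315 with an estimated correlation), and of the inflammatory genes 4 of 8. Of the S phase genes 2 of 19 fell and 17 did not pass (0.00508, 0.722 with an estimated correlation). Adjusted over the list alone, 66 ribosomal genes rose and 3 fell, and 15 immediate early, 10 ERK target and 8 neutrophil granule genes rose.

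In neutrophils the ribosomal genes rpl29, rps29 and rps28 fell, as did the interferon-response gene isg15 and the cytokine gene tnfb. The neutrophils of mcs and prkcda lay largely in different clusters, as given above. Changes in this class may thus come from which cells made it up, which was not tested. The CPM of rpl29 fell from 1882 to 933 (log2 change −1.01 ± 0.09), of isg15 from 48.7 to 3.65 (−3.71 ± 0.38) and of tnfb from 299.7 to 148 (−1.02 ± 0.11). With no filter on low counts isg15 and tnfb had an adjusted p of 0.0818 and 0.0562, and at clustering resolution 2 tnfb changed by −0.23 (adjusted p = 0.159). Of the ribosomal genes 30 of 81 fell and none rose (edgeR, 37 adjusted over the list alone, camera adjusted p = 1.26e-19, 0.568 with an estimated correlation). Of the interferon genes 3 of 11 fell (0.00972, 0.518 with an estimated correlation). ERK target genes went both ways, with 2 of 14 higher and 4 lower (0.00261, 0.400 with an estimated correlation).

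In the erythroid class the neutrophil genes lect2l and lyz, the myeloid transcription factor gene cebpb and the antigen presentation gene mhc1uba rose. The ribosome assembly gene npm1a, the mitochondrial gene c1qbp, the ribosomal gene rpl38 and the embryonic globin gene hbae1.3 fell. A globin-led cluster held 10% of mcs and 32.4% of prkcda erythroid cells. Median UMIs per erythroid cell were 34068 and 21998 in the mcs libraries and 5414 and 6507 in the prkcda libraries. The lyz and lect2l calls recur in 6 classes, and their share of UMIs was also higher in prkcda barcodes under the gene minimum, as given above. Whether depth or RNA from outside the cells gave these changes was not tested. In CPM, lect2l went from 35.2 to 374 (log2 change 3.28 ± 0.20), lyz from 143 to 983 (2.70), cebpb from 7.43 to 61.0 (2.98) and npm1a from 446 to 134 (−1.74). The mcs libraries held 38 and 32 erythroid cells, and without mcs 1 the myeloid genes spi1b and ncf1 and the granule proteoglycan gene srgn, all higher in prkcda, no longer passed (adjusted p = 0.105, 0.198 and 0.105). Of the neutrophil granule list 8 of 9 measured genes rose (camera adjusted p = 1.82e-20, 0.315 with an estimated correlation), of the myeloid list 4 of 4 (4.69e-06, 0.513), and of the inflammatory list 5 of 6 (3.06e-06, 0.384). Of the ribosomal genes 16 of 81 fell (5.03e-04, 0.840 with an estimated correlation). In eosinophils or mast cells the early growth response gene egr1, the cytokine gene il1b, the early response genes fosab and btg2 and the antigen presentation gene cd74a rose, and the protease inhibitor gene spink2.1 and the nucleotide metabolism gene dut fell. The calls of il1b, fosab and btg2 recur in 5 or 6 classes. In CPM, egr1 went from 74.1 to 384 (log2 change 2.37 ± 0.16), il1b from 6.56 to 54.9 (3.03 ± 0.38) and spink2.1 from 1251 to 276 (−2.18). Of the S phase genes 7 of 14 fell (9 adjusted over the list alone, 6.86e-04, 0.423 with an estimated correlation), of the ERK target genes 8 of 11 rose (4.24e-07, 0.315), and of the immediate early genes 9 of 16 rose (6.24e-07, 0.564).

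In tubule cells the respiratory chain gene ndufa4, the oxygen-binding gene mb, the creatine kinase gene ckmt1 and the protein kinase C gene prkcaa fell, and the cytoskeletal gene actn1 rose. The slc12a3 cluster held a smaller part of prkcda than of mcs tubule cells, as given above. Tubule changes may thus come from the tubule segments, which was not tested. On the log2 scale mb changed by −1.63 ± 0.12, and the CPM went from 453 to 66.6 for ndufa4 (−2.77 ± 0.20), from 368 to 80.3 for ckmt1 (−2.19) and from 89.5 to 30.8 for prkcaa (−1.53 ± 0.26). Of the mitochondrial genome genes 6 of 13 fell (camera adjusted p = 0.00373, 0.722 with an estimated correlation), of the ERK target genes 9 of 20 rose (0.0269, 0.474) and of the ribosomal genes 29 of 80 rose and 2 fell (0.00651, 0.855). In multiciliated cells 7 of 10 mitochondrial genome genes rose (2.83e-08, 0.570 with an estimated correlation), as did 6 of 17 immediate early genes (1.70e-09, 0.568). In NK-like cells 14 of 78 ribosomal genes rose (1.90e-09, 0.722 with an estimated correlation), with 1 mcs library that was assumed to vary like the prkcda libraries. Endothelial cells also had 1 mcs library, of 21 cells, and its genes outside the haemoglobin list are not given. No list in this comparison passed with an estimated correlation.

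**Figure D2:**
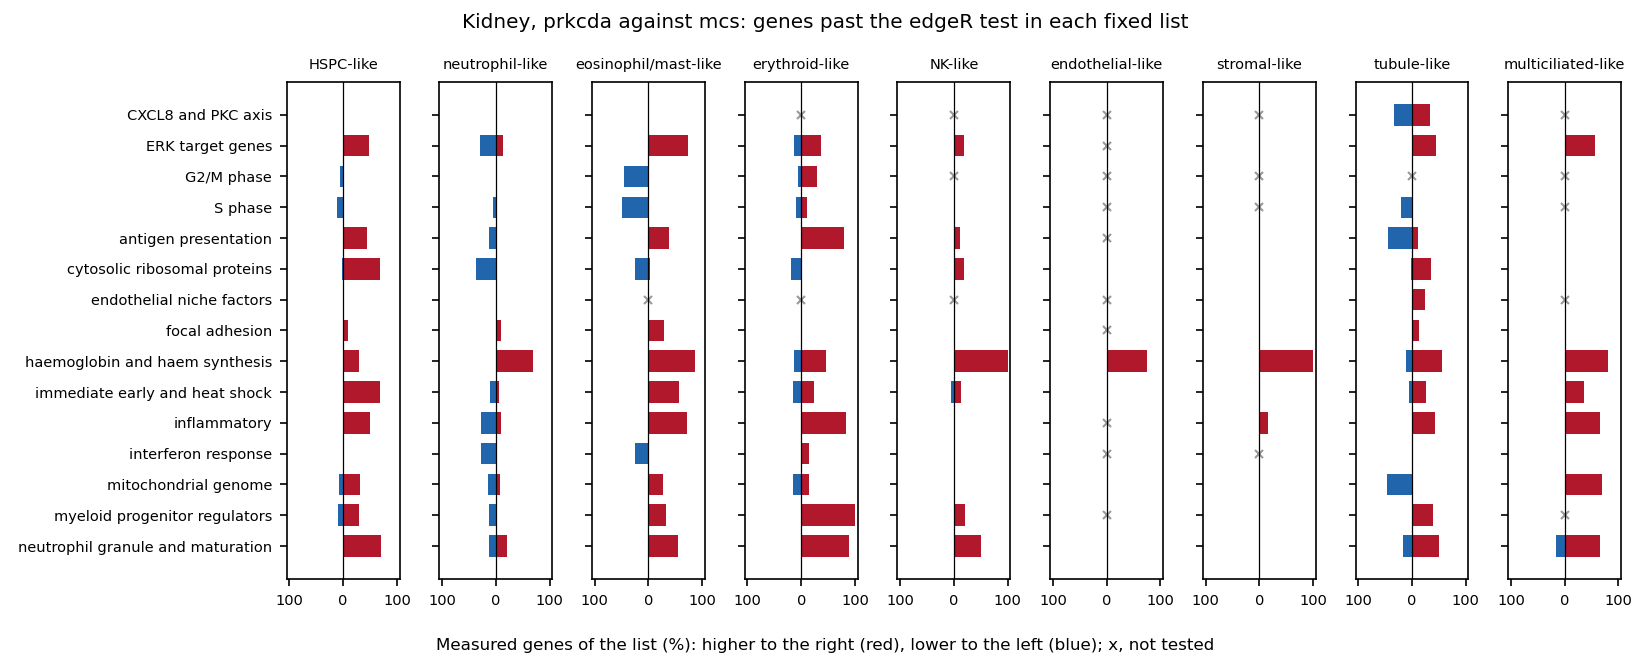
Percent of each list's measured genes that were higher (red, to the right) or lower (blue, to the left) in prkcda, per list and class, with a cross where fewer than 3 genes were measured. Ribosomal genes were higher in HSPC (55 of 81) and lower in neutrophils (30 of 81).

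The comparison of cxcl8 with mcs kidney marrow asks how the tissue differs in the fish labelled with cxcl8, the gene for a chemokine that draws neutrophils. Neutrophils and multiciliated cells made up smaller shares of cxcl8 than of mcs cells, and stromal cells, which include fibroblasts, a larger share, in both cxcl8 libraries against both mcs libraries. Neutrophils made up 23.0% ± 3.0 (SD, n = 2 libraries) in mcs and 9.20% ± 1.49 in cxcl8 (126 and 31 cells, log2 change −1.35 ± 0.30 SE, edgeR adjusted p = 0.00101). Stromal cells made up 3.28% ± 0.66 and 8.34% ± 1.80 (log2 change 1.31 ± 0.48, adjusted p = 0.0313). Without cxcl8 2, mcs 1 or mcs 2 in turn, the stromal change was 1.09, 1.14 and 1.55 and did not pass (adjusted p = 0.190, 0.0954 and 0.0644). Multiciliated cells numbered 21 in mcs and 3 in cxcl8 (log2 change −2.12 ± 0.83, adjusted p = 0.0321). This change was −1.24 without cxcl8 2 and −1.18 without mcs 2, neither passing, and 0.54 with unnamed clusters counted with their best class. Tubule cells (15.5% and 10.0%, adjusted p = 0.0972) and the erythroid class (3.68% and 3.28%, adjusted p = 0.759) did not pass, but tubule cells passed without cxcl8 1 (log2 change −1.13). With barcodes shared between libraries removed, the erythroid change went from −0.19 to −2.51 ± 1.33 (adjusted p = 0.0755). Among haematopoietic classes alone the neutrophil change was −0.23 (adjusted p = 0.428), where only 20 mcs and 11 cxcl8 erythroid cells made up the rest, so a fall could hardly show. These are shares of 543 mcs and 340 cxcl8 cells, of which 50.8% and 68.3% were left without a name. Clusters scoring highest for multiciliated cells but kept out made up 8.76% of mcs and 17.1% of cxcl8, and those for endothelial cells 3.43% and 8.19%.

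In tubule cells the uncoupling protein gene ucp3, the lipid gene acsl4b, the glutamate enzyme gene glud1a and the transcription factor gene cebpd rose in cxcl8. The amine synthesis gene ddc, the peroxidase gene prdx1, the chaperone gene hspa8, the ERK feedback gene dusp6 and the early response genes egr1 and junba fell. Tubule cells alone could be tested, with 24 cells of 1 cxcl8 library, which was assumed to vary like the other groups' libraries, and 251 of 7095 genes passed (104 higher, 147 lower, 1148 at an unadjusted p under 0.05, 94 by DESeq2). Of all cells in that library (cxcl8 1) 30.98% carried a barcode also found in another November library, and with shared barcodes removed 19 of its tubule cells were left and no class could be tested. Relative to a median change over all genes of −0.14, ucp3 went from 106 to 785 CPM (log2 change 2.89 ± 0.27), acsl4b from 236 to 832 (1.82) and ddc from 2701 to 496 (−2.44 ± 0.24). Further falls were from 2144 to 664 in prdx1 (−1.69), from 194 to 20.1 in dusp6 (−3.26) and from 363 to 107 in egr1 (−1.76). The floor of 3 counts over the tubule cells of both cxcl8 libraries was 14.3 CPM without TMM. The dusp6 level in cxcl8 is thus near the floor and rests on few UMIs. A slc12a3 cluster held 46.4% of mcs and 74.3% of cxcl8 tubule cells, and a cluster led by slc6a19b and lrp2a, of the proximal tubule, held 53.6% and 25.7%. Of the immediate early and heat shock genes 4 of 19 fell (6 adjusted over the list alone, camera adjusted p = 0.0390, 0.777 with an estimated correlation). Of the antigen presentation genes 2 of 9 rose, b2m and ctss2.2 (0.0390, 0.777 with an estimated correlation), and without mcs 1 neither passed (adjusted p = 0.104 and 0.124). ERK target genes had 2 of 20 lower (0.0531) and interferon genes 1 of 9 higher (0.0531). Over all cells summed, prkcda fell from 61.12 to 33.197 (log2 change −0.88 ± 0.17, adjusted p = 0.00974), as did 11 of 15 neutrophil granule genes and 12 of 19 S phase genes, whose camera adjusted p was 0.186 each with an estimated correlation. These sums mix classes, and the neutrophil share was lower in cxcl8. Within neutrophils prkcda was at 235 and 295 CPM without TMM in the mcs libraries and at 356 and 191 in the cxcl8 libraries. Over all cells cxcl8a had 4 UMIs in mcs and 1 in cxcl8, and cxcl8b.1 had 30 (25 of them in mcs 2) and 1. Without TMM cxcl8b.1 was at 9.95 CPM in mcs and 0.71 in cxcl8, the latter below the floor of 2.33. Neither gene was higher in the libraries labelled cxcl8.

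The difference between the prkcda and cxcl8 effects was tested for shares and for tubule genes, each against its own mcs libraries. The shares differed for erythroid cells (log2 difference 3.03 ± 0.62 SE, edgeR adjusted p = 2.34e-04), neutrophils (2.05 ± 0.30, adjusted p = 4.93e-06) and stromal cells (−1.34 ± 0.52, adjusted p = 0.0291), but not for tubule (−0.46, adjusted p = 0.20) or multiciliated cells (1.6997, adjusted p = 0.0844). In tubule cells ddc, prdx1, zgc:158445, hspa8, egr1 and dusp6 rose in prkcda and fell in cxcl8. The genes ucp3, mb and arg2, an arginine enzyme gene, fell in prkcda and rose in cxcl8. The bile acid enzyme gene cyp7a1 rose in prkcda (2.999) and did not pass in cxcl8 (−0.66). Of 7095 genes 767 differed (485 with the prkcda effect above the cxcl8 effect, 282 below, 436 by DESeq2), about a median of 0.17, and this rests on the lone cxcl8 library of 24 cells, assumed to vary like the others. The tubule clusters moved apart too, the slc12a3 cluster from 42.0% to 16.6% of tubule cells in prkcda and from 46.4% to 74.3% in cxcl8, and the lrp2a clusters of the proximal tubule from 16.95% to 29.0% and from 53.6% to 25.7%. For ddc the log2 changes were 1.64 and −2.44 (difference 4.08 ± 0.29), for ucp3 −2.51 and 2.89 (−5.40 ± 0.41), for mb −1.63 and 0.84 (−2.47) and for dusp6 0.88 and −3.26 (4.14). The cxcl8 change of dusp6 rests on a level near the floor, as given above. By list, 5 of 20 ERK target genes (camera adjusted p = 0.00880, 0.602 with an estimated correlation) and 6 of 19 immediate early genes (0.0208, 0.712) differed upward. For the mitochondrial genome 5 of 13 differed downward (0.00173, 0.712 with an estimated correlation), as did 2 of 9 antigen presentation genes (0.00880, 0.687) and 1 of 9 interferon genes (0.0365, 0.687). No control library was shared, so the experiment and the label differ together.

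**Figure D3:**
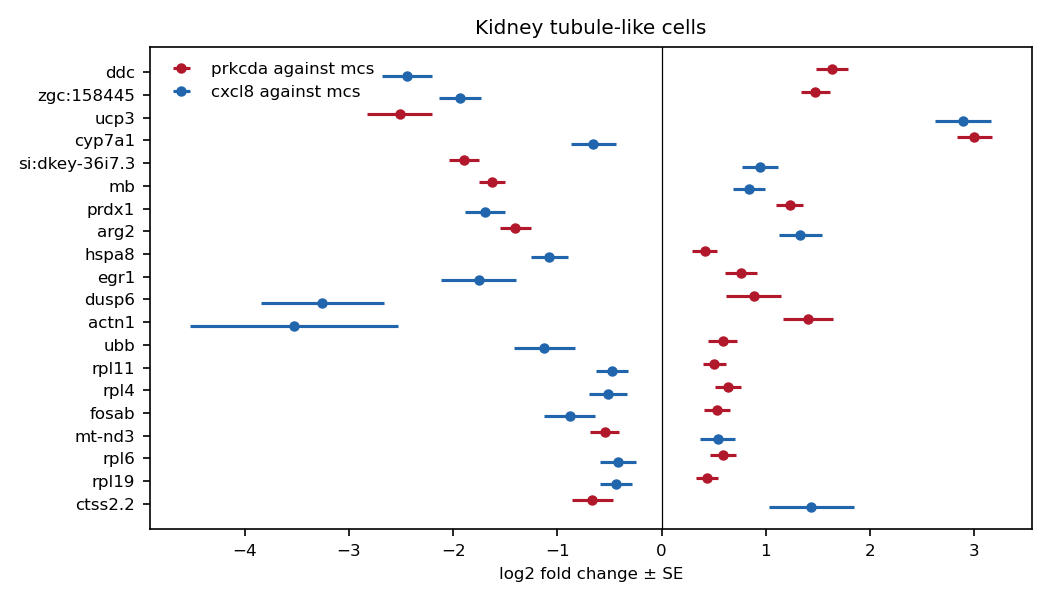
Log2 change (horizontal axis) with its SE in kidney tubule cells for the prkcda (red) and cxcl8 (blue) comparisons, each against its own mcs libraries, for 20 genes whose changes differed. The changes of ddc lay at 1.64 and −2.44, and those of ucp3 at −2.51 and 2.89.

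The comparison of cxcl8 with control embryos asks how whole embryos with the cxcl8 label differ. Neither epidermis, neutrophils, macrophages nor any other of 12 classes passed the edgeR test of shares with the experiment as a term (every adjusted p 0.999, 0 at an unadjusted p under 0.05). Neutrophils made up 0.83% of control and 0.51% of cxcl8 cells in runx and 0.33% and 1.47% in August. Macrophages made up 1.39% and 1.47% in runx and 0.48% and 1.44% in August. Epidermis went from 48.9% to 62.2% in runx and from 47.8% to 37.7% in August. There, clusters led by rhcgl1 and krt17, by hsp90b1 and tnfb, and by bhlha9 and mslna held 37.9%, 17.0% and 13.6% of control epidermis and 0.29%, 0.55% and 0.50% of cxcl8 epidermis. Clusters led by ponzr3 and by slc6a19b and krt97 held 15.4% and 8.83% of control and 51.0% and 34.4% of cxcl8 epidermis. Cells without a name made up 24.4% and 17.3% in runx and 44.4% and 49.98% in August, where clusters scoring for epidermis but kept out held 23.0% and 35.5% and those for skeletal muscle 13.6% and 0.22%. Of 42124 pairs of gene and class over 9 classes, 149 passed (60 higher, 89 lower, 1832 at an unadjusted p under 0.05, 16 by DESeq2). They lay in mesenchyme or fibroblasts (25 higher, 29 lower), mucous or secretory cells (17 and 21), ionocytes (6 and 36) and pigment cells (12 and 3). Epidermis, intestine, macrophages, neutrophils and muscle had none by edgeR, with 682, 124, 43, 15 and 37 at an unadjusted p under 0.05.

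In mesenchyme or fibroblasts the matrix genes coch and col9a3, the growth-factor binding gene fgfbp2b, the chemokine gene cxcl12b and the proteoglycan gene srgn rose in cxcl8 embryos. The dividing-cell genes ube2c, top2a, cdk1, nusap1 and kpna2, the secretory gene agr2 and the muscle actin gene actc1b fell. The class pools unlike clusters across experiments, since a cluster led by zgc:136930 and si:dkey-183i3.5 held 49.3% of August control mesenchyme, while in runx a cluster led by these genes was named epidermis. The CPM of coch went from 1.06 to 108 (log2 change 6.57 ± 0.58, adjusted p = 1.71e-25), of col9a3 from 3.38 to 65.6 (4.33) and of cxcl12b from 20.1 to 62.1 (2.02). Of the G2/M phase genes 7 of 14 fell (13 adjusted over the list alone, camera adjusted p = 1.08e-27, 0.948 with an estimated correlation), with top2a at −2.18 and cdk1 at −1.99. Of 16 S phase genes none passed by edgeR (4 adjusted over the list alone, 2.43e-08, 0.948 with an estimated correlation), and of 12 niche factor genes 1 rose (3.68e-04, 0.948). In ionocytes, the ion-transporting skin cells, zgc:77439 fell from 145 to 11.4 (−3.45), igf2b, a growth factor gene, from 96.4 to 26.0 (−1.85), and the actin-binding gene tagln2 (−2.66) and the adhesion gene pxna (−2.05) fell, while agr2 (2.45) and galr1b (2.87) rose. A cluster led by s100a11 held 27 of the August control ionocytes and 1 of the August cxcl8 ionocytes. In mucous cells the keratin gene krt97 fell from 372 to 74.6 (−2.31), with rpa3 (−1.69) and the ERK feedback gene spry2 (−1.59), and 2 of 10 S phase genes fell (2.17e-04, 0.948 with an estimated correlation). In pigment cells aqp1a.1, a water channel gene, rose from 19.2 to 437 (4.78), SYNPR from 4.93 to 341 (5.40) and cd9b by 3.99, and the replication gene pcna fell from 284 to 29.0 (−3.27). This class too pools unlike cells, since the glial genes cd59, plp1b and mbpa are among the 10 leading genes of the August pigment cluster, while in runx they lead a separate glial cluster. Neither cxcl8a (ENSDARG00000104795, over all cells summed 0.14) nor prkcda (0.36) passed (adjusted p = 1). Without control 1, control 2, cxcl8 1 and cxcl8 2 in turn, 97, 50, 228 and 13 pairs passed, of which 5, 8, 22 and 0 were among the 149, and those fits lacked the experiment term.

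The comparison of HUVEC given CXCL8 with HUVEC given PBS asks how endothelial cells respond to the chemokine. No gene passed by edgeR among 15313 tested (592 at an unadjusted p under 0.05, 142 by DESeq2, 4 by limma-trend), so the values that follow are differences of means between 2 and 2 libraries. The antiviral genes MX1, MX2, IFIT2 and RSAD2 were higher with CXCL8, and so were RELB, TRAF1, CSF1 and NFKBIA of the NF-kB list, the transcription factor genes EGR1, EGR3, FOS, FOSB and FOSL1, and SPRY4, an ERK feedback gene. ESM1 and PLAU of the angiogenesis list and BMP2 of the niche factor list were higher too. The low-oxygen genes EGLN3, ANKRD37 and PDK1, the arterial gene GJA5 and IGFBP3, also of the niche factor list, were lower. The CPM of MX1 were 15.04 ± 1.21 (SD) with PBS and 211 ± 28 with CXCL8 (log2 difference 3.81 ± 0.21 SE, adjusted p = 0.0825, 6.26e-42 by DESeq2). They were 4.18 and 48.3 for IFIT2 (3.53 ± 0.23, adjusted p = 0.114), 3.77 and 25.7 for RELB (2.77 ± 0.24, adjusted p = 0.180), 1.33 and 21.7 for TRAF1 (4.04 ± 0.40, adjusted p = 0.196) and 27.2 and 86.0 for NFKBIA (1.66 ± 0.18, adjusted p = 0.201). They were 37.6 and 9.97 for EGLN3 (−1.92), 91.3 and 49.6 for IGFBP3 (−0.88), 18.4 and 59.5 for ESM1 (1.69) and 0.43 and 3.50 for EGR1 (3.05 ± 0.50). CXCL8 itself (ENSG00000169429.10) was at 11.2 ± 5.2 and 58.3 ± 2.8 (2.38 ± 0.38, adjusted p = 0.363, 1.33e-06 by DESeq2). PRKCD (ENSG00000163932.13) was at 12.6 and 16.8 (0.41 ± 0.23, adjusted p = 1), and the receptor genes CXCR1 and CXCR2 had 1 count each over the 4 libraries and were not tested.

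By list, 27 of 27 interferon genes (median log2 difference 1.94, camera adjusted p = 2.40e-133) and 29 of 29 NF-kB and inflammatory genes (2.45, 2.08e-117) were higher with CXCL8, and 21 and 26 of them passed adjusted over the list alone. With an estimated correlation their adjusted p was 0.0700 and 0.123. Of the immediate early genes 18 of 21 were higher and 8 passed over the list alone (2.38e-22, 0.123 with an estimated correlation), and of the ERK target genes 17 of 23 and 5 (2.13e-07, 0.123). The cholesterol list had 19 of 20 higher (4.98e-07, 0.123 with an estimated correlation), heat shock 11 of 11 (3.96e-05, 0.136), the unfolded protein response 14 of 16 (3.55e-04, 0.225) and angiogenesis 17 of 27 (3.99e-06, 0.136). Of the hypoxia and glycolysis genes 15 of 18 were lower and 3 passed over the list alone (6.72e-09, 0.225 with an estimated correlation). Fry gave an adjusted p of 0.012 for the interferon, ERK target, cholesterol and heat shock lists, 0.061 for NF-kB, 0.0882 for immediate early genes, 0.147 for the unfolded protein response and angiogenesis and 0.230 for hypoxia. No call was made by camera for niche factors (adjusted p = 0.0632), the CXCL8 axis (0.110), focal adhesion (0.569), endothelial identity, Notch targets, S phase or G2/M phase. Nor was a call made for histones, ribosomal proteins, the mitochondrial genome, the smooth muscle and fibroblast list or the epithelial list. The leukocyte list had fewer than 3 measured members and was not tested. Without each library in turn 5495 (control 1), 1242 (control 2), 60 (CXCL8 1) and 61 (CXCL8 2) genes passed. The libraries of the PBS group differed most (chi-square per degree of freedom 158.88, against 15.79 within CXCL8).

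**Figure D4:**
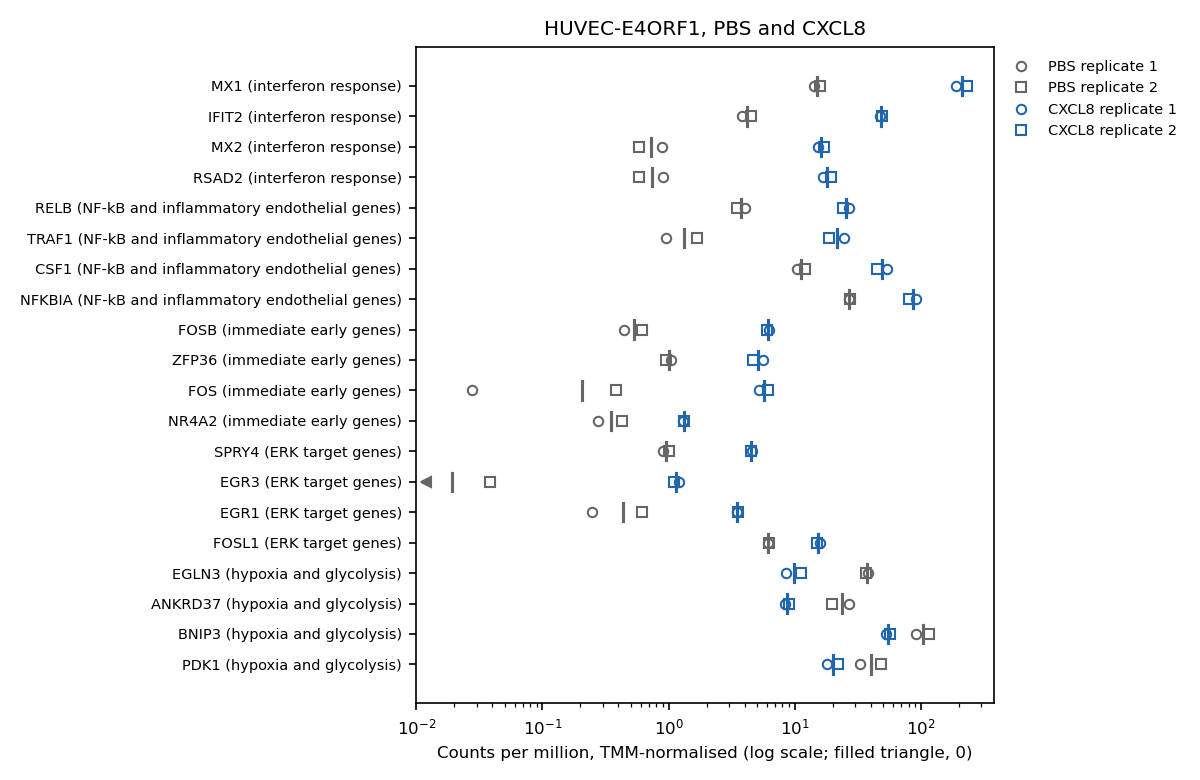
CPM (log axis) of 20 genes of 5 lists in the PBS (grey) and CXCL8 (blue) libraries, with circles for replicate 1, squares for replicate 2, vertical bars at the means and a filled triangle for a count of 0. The means of MX1 were 15.04 and 211, and those of EGLN3 37.6 and 9.97.

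HUVEC ATAC had no treatment groups in the labels, so its 3 libraries were compared with each other. They held 149902, 173378 and 135368 merged peaks over 56.2, 63.4 and 56.7 megabases, with median widths of 270, 268 and 321 bases. The share of a library's peaks overlapped by another's was 65.1% ± 8.3 (SD over 6 ordered pairs, from 54.1% to 78.6%). Of 246611 merged regions, 85545 (34.7%) were seen in all 3 libraries and 130951 in 1.

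For kidney marrow single-cell ATAC the question is whether accessible regions differ between prkcda and mcs, and with 1 library each no test was possible. The mcs library held 490 cells with a median of 3851 counts and the prkcda library 472 with a median of 5737. Of 52283 mcs peaks 73.7% (exact 95% interval 73.3 to 74.1) overlapped a prkcda peak, and of 50687 prkcda peaks 75.9% (75.5 to 76.3) overlapped an mcs peak. Cells with at least 1000 counts made up 74.3% of mcs and 70.8% of prkcda.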

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

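Of the tests below, the hbaa1 share over all classes and the gene length trend were set out before their results were seen, and the other 8 tests were chosen after. The differences between the prkcda and cxcl8 effects drew attention because the test of the difference itself passed (edgeR). They were 3.03 on the log2 scale for the erythroid share, 2.05 for the neutrophil share and −1.34 for the stromal share, and 767 tubule genes differed, among them ddc, ucp3 and dusp6. No control library was shared between July and November, so these differences could come from the experiment as well as from the labels. The dusp6 level in cxcl8 tubule cells was near the floor, as given above. The tubule count was 436 by DESeq2, rests on a lone cxcl8 library of 24 cells, and may also come from tubule segments, since the slc12a3 cluster went from 42.0% to 16.6% of tubule cells in prkcda and from 46.4% to 74.3% in cxcl8. In the November cxcl8 libraries 30.98% and 32.05% of cells carried a barcode also found in another November library, with index hopping or shared ambient barcodes left open and untested, and without such barcodes the erythroid change there was −2.51 and no gene test could be run. Haemoglobin transcripts made up 4.05% and 4.33% of UMIs in barcodes under the gene minimum of the prkcda libraries, which no comparison uses, against 0.15% and 0.10% in the mcs libraries.

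The haemoglobin genes hbaa1 and hbba1 (ENSDARG00000089087) were called higher in 9 of 9 tested classes of the prkcda libraries. Doublets with red cells are argued against as the whole cause, since 100% of prkcda neutrophils held a haemoglobin UMI, and expression by neutrophils themselves is argued against, since barcodes under the gene minimum held 0.913 of the neutrophils' median. If free RNA were the source, hbaa1 would make up the same share of haemoglobin UMIs in every class as in those barcodes, and outside HSPC the shares lay within 2.14 percentage points. Those barcodes had been called cells and held mostly mitochondrial UMIs, so how well they stand for free RNA was not tested. HSPC were set apart only after their gap was seen, so that value decides nothing for the other classes. In prkcda HSPC the hbaa1 share was 42.1% (exact 95% interval 41.2 to 42.9) against 35.2% (34.5 to 35.9) in 1 library. It was 43.1% against 36.5% in the other, a gap of at least 6.60 points. That gap argues against free RNA as the whole source of haemoglobin UMIs in prkcda HSPC. In mcs the shares also lay apart, at 49.5% and 53.4% in HSPC against 44.3% and 40.8% in barcodes under the gene minimum. The gap therefore cannot decide whether free RNA gave the rise over mcs. Over all classes the largest gap was 6.88 points, between the bounds set for either reading. By the hbaa1 share, free RNA and a further source thus cannot be told apart for the classes as a whole. Median haemoglobin UMIs per cell ran from 32 to 46 over the non-erythroid classes of the prkcda libraries and from 0 to 2 in mcs. The prkcda barcodes under the gene minimum held medians of 38 and 42. So high a level there argues against expression by the cells themselves as the source of the rise in these medians.

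In HUVEC 24 of 29 NF-kB genes of PBS replicate 2, such as SELE, VCAM1 and BIRC3, lay between PBS replicate 1 and the CXCL8 libraries, and 5, RELB among them, lay at or below PBS replicate 1. A mixture with CXCL8 material would give interferon genes such as MX1 the same implied share as NF-kB genes. The medians were −1.97% over 19 interferon genes (quartiles −19.5 and 3.89) and 8.57% over 22 NF-kB genes (quartiles 3.94 and 18.6), a gap of 10.54 percentage points that argues, narrowly, against mixing as the whole cause. Removing the trend of the ratio of PBS 2 to PBS 1 on gene length left 118% of the NF-kB genes' median log2 ratio, from 0.91 to 1.07 over 29 genes, which argues against gene length. No biological explanation was tested, and a difference between the cultures may remain, since neither 10.54 points nor 118% addresses it.

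Shares of erythroid cells, neutrophils and HSPC differed in prkcda kidney marrow, where the protocol lysed red cells. Leftover red cells would lower the neutrophil share, which was higher by 0.71 on the log2 scale with them in the total. More leftover red cells in prkcda are therefore argued against as its cause. Without them the change was 0.86, which had to exceed 0.71 because the erythroid share was higher in prkcda, and so adds nothing. For the erythroid share itself unequal lysis stays open and untested. Less kidney tissue in the prkcda samples would move erythroid cells and neutrophils alike within haematopoietic classes. There their log2 changes of 2.35 and 0.21 lay 2.14 apart, which argues against it as the whole cause of the erythroid change. For neutrophils that gap decides nothing, since it rests on the erythroid share. Their change went from 0.71 in all cells to 0.21 there. That total keeps the erythroid cells, whose share was higher in prkcda, so the drop to 0.21 mixes their rise with any loss of kidney tissue. How much of the neutrophil change may come from less kidney tissue was not tested. With best-class naming, tubule cells made up 22.6% of mcs and 7.57% of prkcda cells, and multiciliated cells 18.9% and 7.52%. For HSPC, counting unnamed clusters with their best class took the log2 change to −0.13, so the fall may come from the naming thresholds. An effect of the prkcda label on erythroid and neutrophil numbers stays open and untested beside these.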

How the results depend on the processing

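Tests with all cells summed, crossed replicate numbers, shared barcodes removed, haematopoietic classes only, all deposited barcodes or best-class naming were chosen after the result was seen, and the other alternatives were planned. In prkcda kidney marrow the erythroid, neutrophil and tubule calls kept their direction and side of the threshold in every alternative run, with log2 changes from 1.87 to 3.11 for erythroid cells, 0.21 to 0.98 for neutrophils and −1.58 to −0.89 for tubule cells. For HSPC the change was −0.36 at resolution 2, −0.40 with stricter cell filters and −0.38 with doublets kept, and with best-class naming it was −0.125 and did not pass. NK-like cells did not pass among haematopoietic classes (0.788) and ranged from 0.908 to 1.778 without each library. The eosinophil or mast cell share reversed to −0.448 at resolution 2 and passed there, and passed at 0.32 without erythroid cells and 0.31 with all deposited barcodes. Multiciliated cells, which did not pass, ranged from −1.33 to −0.21 and thrombocytes from −1.37 to −0.59, each passing in some alternatives.

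In the cxcl8 comparison 3 class shares passed, against 1 with the replicate block, 1 with only the 4 libraries of the experiment, 0 among haematopoietic classes, and 1 to 4 without each library. Multiciliated cells did not pass with stricter cell filters (−1.536), with the block (−2.055), with only the 4 libraries (−2.063) or with shared barcodes removed (−1.873), reversed with best-class naming (0.542), and ranged from −8.966 to −1.179 without each library, the lowest being a fit to 0 of 156 cells in cxcl8 2 (upper 95% limit 2.34%) and so no bound. Stromal cells did not pass with the block (1.346) or the 4 libraries (1.298), ranged from 1.090 to 1.548 without each library, and their difference between effects was −1.371 with the block. Neutrophils did not pass among haematopoietic classes (−0.226), where erythroid cells were the only other class. The erythroid change, −0.19, was −2.51 with shared barcodes removed, and the erythroid difference between effects was not run that way. Tubule cells passed with stricter cell filters (−2.49), with doublets kept (−1.48) and without cxcl8 1 (−1.13). No embryo share passed in any alternative run.

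Gene counts moved more. The HUVEC count of 0 was 142 by DESeq2, 252 with no filter, 293 with the block, 4 by limma-trend, 0 with DESeq2 size factors in edgeR, and 60 to 5495 without each library. The prkcda count of 4615 was 1811 by DESeq2, 2911 to 3695 without each library, and 3449 to 5694 otherwise, with 4249 when the replicate numbers were crossed as the block. The cxcl8 tubule count of 251 was 94 by DESeq2, 390 with the block, 1919 genes with all cells summed, and 240 to 270 otherwise. The embryo count of 149 was 16 by DESeq2, 401 with no filter, 0 without the experiment term, 97 with doublets kept, 0 with all cells summed, 112 at resolution 2 and 13 to 228 without each library. The difference count of 767 was 436 by DESeq2 and 885 with the block. With an estimated correlation the lists passing numbered 0 in HUVEC, 0 in each kidney comparison and 0 in embryos. That setting also rests on few residual degrees of freedom, 2 in HUVEC. There the correlation estimated for the ERK target, cholesterol and heat shock lists was −0.0226, −0.0366 and −0.0335, below the preset 0.01. Their unadjusted camera p still rose, from 5.08e-08 to 0.0265 for ERK target genes. These failures thus cannot show whether correlation between genes removed a call. In HUVEC the niche factor list, which did not pass, had an adjusted p of 0.00105 with the block.

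Of the named genes' values in HUVEC 523 stayed on their side of the threshold and 223 passed newly, and in the embryo comparison 556 stayed, 297 no longer passed, 7 passed newly and 9 reversed. In the prkcda comparison 1103 stayed and 61 no longer passed, and in the cxcl8 comparison 396 stayed and 18 no longer passed. Those that reversed are given as ranges without each library. In ionocytes cfd ranged from −11.167 to 3.223 and fn1b from −4.388 to 6.222 (0.065 by DESeq2), the highest without control 1. In mesenchyme si:dkey-33i11.4 ranged from −3.967 to 0.995, the highest without control 2. In mucous cells cfd ranged from −8.713 to 3.074 and rrm2 from −8.135 to 7.413, the highest without control 1, and ndufa4 from −5.458 to 8.853, gsta.2 from −5.542 to 8.706 and gstm.3 from −1.622 to 4.068, the lowest without cxcl8 1.

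The overlap of HUVEC ATAC peaks, 65.1%, was 77.825% with a q-value under 0.01, 88.364% for the strongest 50000, 55.502% with reciprocal overlap and 58.605% to 69.99% without each library. The overlap of prkcda with mcs peaks in single cells was 61.408% with reciprocal overlap. With cells of at least 1000 counts the medians were 6020 in mcs and 10218 in prkcda. For these results the cause was not tested, except that fits without a library hold fewer samples, with a lone library assumed to vary like the other groups. In the November genes, doublets kept, shared barcodes removed and leaving out cxcl8 1 left no class that could be tested, and peaks at listed genes and accessibility of marker genes were not run. The small number of usable cells limits November most, with 24 cxcl8 tubule cells tested.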

Other observations

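The tests in this part were chosen after the result was seen. In November, the barcodes of 31.0% and 32.1% of cells in the cxcl8 libraries and of 22.5% and 14.97% in the mcs libraries also occurred in another library, against at most 0.79% in July and in the embryo libraries. The reporter gene dsred_gestalt was at 7.35 CPM in July mcs and 1.85 in July prkcda over all cells summed (log2 change −1.98, edgeR adjusted p = 0.00210). That sum mixes classes whose shares differed: in tubule cells the gene was at 23.6 ± 17.8 CPM without TMM in mcs (mean and SD of 2 libraries, 61 and 17 UMIs) and 3.25 ± 2.02 in prkcda (1 and 3 UMIs), and in neutrophils at 2.93 ± 1.39 and 2.78 ± 0.02. Embryo cxcl8a went from 156 to 126 CPM without TMM in runx and from 2.99 to 3.89 in August, control before cxcl8.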
